A study of Mus musculus with 4 samples.

How the data were processed

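The data were 4 single-cell RNA sequencing libraries of CD45+ cells sorted from mouse back skin, 1 each for control (CT) and prenatally stressed (PS) offspring at 8 and 24 weeks. Per the labels' protocols, dams of PS offspring were restrained 3 times a day for 30 minutes late in gestation, each library pooled 3 mice, and libraries were made with 10x Genomics 3′ v3.1 chemistry. The labels speak of mice of both sexes without giving the sex of each pool; in the counts, Y-linked UMIs were found in 84.59, 84.14, 86.74 and 81.29% of cells (CT and PS at 8 weeks, then CT and PS at 24 weeks) and an Xist UMI in 13 cells of all libraries. The deposited values are raw UMI counts per gene and cell barcode, after cell calling by Cell Ranger on mm10 per the submitters' processing notes, which also name Seurat 4.3.0. The Cell Ranger version is not given in the sources used here. The lowest UMI total of any barcode was 500.

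The 4 matrices listed 32285 genes and 28015 barcodes. Cells with under 200 genes, under 500 UMIs or over 10% mitochondrial UMIs were removed, which left 7211, 4473, 6809 and 9003 in the order above. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 0.022% of cells in PS at 8 weeks and 0.015% in CT at 24 weeks, so the cells with the highest scores were removed instead, up to an expected rate of 0.8% per 1000 cells; this was chosen after those values were seen. It removed 416, 160, 371 and 648 cells and left 25901. Median mitochondrial percentages of the kept cells were 2.13, 2.18, 1.66 and 1.78. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen within libraries were reduced to 30 principal components without batch correction. A graph of 15 neighbours was clustered by the Leiden method at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, seed 1).

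Marker genes, gene lists, comparisons and alternatives were written down before the data were examined. A cluster took the name of the class whose markers had the highest mean log2 level over the other clusters, if that score was at least 0.75 with 3 or more markers detected in 10% of its cells. The natural killer and innate lymphoid cell classes were allowed at most 600 CPM of Cd3e plus Cd3g. This limit did not apply to cycling cells, of which cluster 18 was at 3179 CPM. Among its 10 leading genes a cluster also needed at least as many markers of its class as markers found only on another class's list. Clusters that failed any of these rules kept their number. Cluster 4 scored 1.41 but had 1 marker of its class there against 2 of another.

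Shares of kept cells have exact binomial (Clopper-Pearson) intervals. UMIs were summed per class and library and given as CPM with exact Poisson intervals, and ratios have exact conditional binomial intervals (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). With 0 UMIs in one library, the ratio uses a floor of 3 counts and is given as a lower limit. A gene was eligible for naming in a class if it had at least 30 UMIs in both libraries together, at least 100 CPM in the higher one, and an interval wholly beyond 1.5-fold. Sex-linked, mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, unnamed gene models, and genes under 10% of their CPM in the class with most were left out. Of eligible genes, those with the largest ratios were named: 12 each way in mast cells and 4 in other classes of at least 100 cells between PS and CT, and 6 and 3 between ages. List members with the largest ratios were named as well, up to 4 per list, and genes past the edgeR test up to 10 each way. A result that this rule names in Langerhans cells is left out on request, so the account of that class is incomplete. Values given beyond this rule were chosen after they were seen. They are those of Il4 and Cpa3 in mast cells at 8 weeks, Il13 and Csf2 there at 24 weeks, Mrc1, Ccl22, Ifit1 and Ifi27l2a in macrophages, Isg15 in αβ T cells, the repeats of mast cell genes without second-type cells, some members given at a second age or in CT beside PS, the T cell receptor genes, the genes compared between cluster 28 and dendritic epidermal T cells, Il17a and Il1r1 in dermal γδ T cells, Ubb and Sap18 across classes, and Gm47283. Which shares of cell classes are described was also chosen after they were seen.

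Each fixed list with at least 5 measured members was summarised by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on expression in 20 bins. Percentiles describe these libraries only. For mast cells every measured list is reported between PS and CT. For other classes lists are reported if they lie beyond the 2.5 or 97.5 percentile with a median of at least 1.5-fold, and for age if they do so in the same direction in CT and PS. Lists that differ in opposite directions at the 2 ages are reported too. This reporting rule was chosen after the values were seen.

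Mast-class cells were counted as carrying transcripts of a second type if they had at least 20 UMIs of MHC class II genes (Cd74, H2-Aa, H2-Ab1), 5 of T cell genes or 5 of complement C1q genes, limits chosen after the data were seen. Of 570 mast-class cells, 25 had 10 to 40 UMIs of the MHC class II genes. To compare detection between depths, cells were thinned to 1000 UMIs, and shallower cells were left out.

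Over all 4 libraries, UMI sums of mast cells and macrophages were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, terms for age and stress), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Biological coefficients of variation were 0.172 and 0.160. On simulated counts of the mast cell class the test found 83.5% of genes changed 4-fold and 11.0% of those changed 2-fold, with 2 false calls among 92. For macrophages it found 91.6% and 24.1%, with 4 false calls among 123. On simulated Poisson counts, the model that the ratio intervals assume, these covered the true value for 95.77 to 96.55% of genes. The simulation had no spread between cells or pools. Coverage for real genes whose UMIs lie in few cells was not tested. The naming rule picked 88.0 to 96.2% of 4-fold and 33.0 to 63.3% of 2-fold differences.

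Alternatives were a stricter filter (500 genes, 1000 UMIs, 5% mitochondrial), doublets kept, Leiden resolution 2, variable genes over all cells, cells with Y-linked UMIs only, other denominators and depths, TMM scaling, other limits for named genes, equal weight per cell, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, and models with 1 term. Shared sequence was searched in the last 400 bases of transcripts in GENCODE M21 (mm10) in windows of 60 bases. Figures were drawn with matplotlib 3.10.9.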

Results

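The data were single-cell RNA sequencing counts of CD45+ immune cells sorted from the back skin of C57BL/6J mice. Pregnant dams were either restrained repeatedly in the last part of gestation or left undisturbed, and the skin of their offspring was taken at 8 or 24 weeks of age. The 4 groups were control offspring (CT) and prenatally stressed offspring (PS) at each age, with 1 library per group made from a pool of 3 mice. The comparisons asked how the immune cells of adult skin differ after prenatal stress, with attention to mast cells, which the title of the series names. The libraries held 7324 barcodes and 44560460 unique molecular identifiers (UMIs) in CT at 8 weeks, 4567 and 35495699 in PS at 8 weeks, 6980 and 58472707 in CT at 24 weeks, and 9144 and 51984586 in PS at 24 weeks. After filtering, 6795, 4313, 6438 and 8355 cells remained in the same order, with median depths of 4725, 6072, 6506 and 4030 UMIs per cell. Because each group was 1 library, differences between groups had no replicate check. The 95% intervals given with shares and folds cover counting error only.

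Clustering gave 29 clusters, of which 26 received a class name. A class name here means clusters that resemble that cell type by marker genes fixed in advance. Dendritic epidermal T cells, the γδ T cells that reside in mouse epidermis, were led by Trdc, Trdv4 and Tcrg-C1. Langerhans cells were led by Cd207, macrophages by Ccl8, Pf4, C1qc and C1qb, mast cells by Mcpt4, Cma1, Cpa3 and Tpsb2, and dermal γδ T cells by Il23r, Blk and Il17a. Natural killer cells were led by Gzma and Klra8, group 2 innate lymphoid cells by Gata3, Il5 and Il13, and neutrophils by S100a8 and S100a9. Clusters 4, 10 and 28 were kept by number. Cluster 4 was led by Tnfrsf4, Ctla4 and Foxp3, cluster 10 by Retnla, Lyz1 and Fn1, and cluster 28 by Lhfpl3, Adarb2 and Cd163l1.

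In PS skin at 8 weeks, macrophages and natural killer cells took larger shares of the CD45+ cells than in CT skin, and dendritic epidermal T cells a smaller one. Macrophages were 9.92% of cells (95% interval 9.05 to 10.9) against 5.95% (5.40 to 6.53), a ratio of 1.67 (1.45 to 1.92). Natural killer cells were 5.89% against 4.12%, a ratio of 1.43 (1.20 to 1.70). Dendritic epidermal T cells were 39.1% (37.7 to 40.6) against 47.7% (46.5 to 48.9). Neutrophils were 1.72% against 0.780%, a ratio of 2.20 (1.53 to 3.19), and conventional dendritic cells 1 were 2.11% against 1.49%. Mast cells were 1.07% (0.782 to 1.42) of PS cells and 1.16% (0.922 to 1.45) of CT cells, a difference within counting error. Without mast-class cells that carried many transcripts of a second cell type they were 0.606% and 0.959%, a ratio of 0.632 (0.385 to 1.01) from 26 and 65 cells.

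At 24 weeks the macrophage and natural killer cell shares were again higher in PS, and mast cells and neutrophils were lower. Macrophages were 8.83% (8.23 to 9.46) against 5.73% (5.18 to 6.33), a ratio of 1.54 (1.36 to 1.75), and natural killer cells 5.98% against 3.45%, a ratio of 1.74 (1.48 to 2.04). Mast cells were 2.18% (1.88 to 2.52) in PS against 4.09% (3.615 to 4.598) in CT, a ratio of 0.533 (0.439 to 0.647). Their median depth at 24 weeks was 1059 UMIs in PS and 1555 in CT, near the minimum of 500 UMIs per cell, so the filter and the depth gap can set this share. Neutrophils were 0.634% against 2.84%, a ratio of 0.223 (0.161 to 0.305), also at low median depths of 1627 and 2788 UMIs. Dermal γδ T cells were 7.11% against 4.46%, a ratio of 1.60 (1.38 to 1.84), and αβ T cells 12.3% against 10.1%. The named dendritic epidermal T cell clusters held 11.6% (10.9 to 12.3) against 27.5% (26.4 to 28.6). With cluster 28, where the T cell receptor component gene Cd3e was at 2170 CPM (counts scaled to the UMI total of the class) against 2026 in the named clusters of the same library and Trdv4 at 93.2 against 381, the shares were 22.7% and 28.4%, a ratio of 0.801 (0.7503 to 0.8541). Of the 998 cells of cluster 28, 93.39% came from the PS 24-week library.

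**Figure D1:**
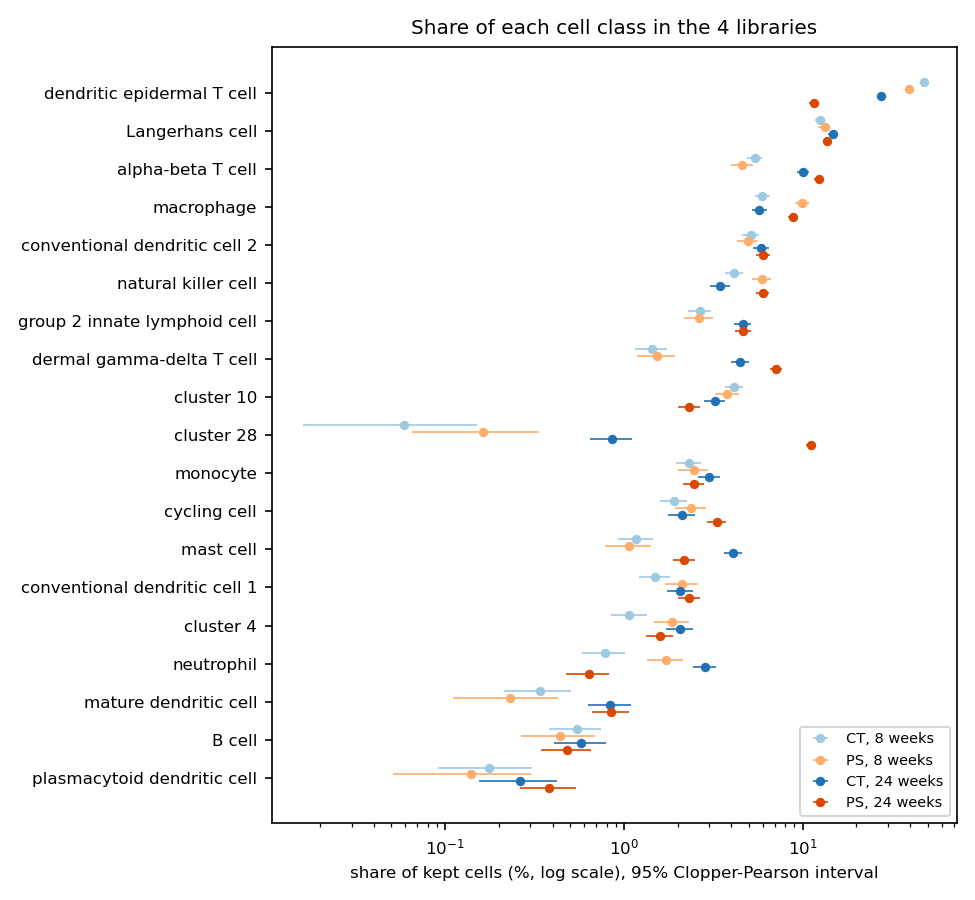
Share of kept cells (percent, log scale) for each cell class and numbered cluster in the 4 libraries, with 95% Clopper-Pearson intervals; colours mark CT and PS at 8 and 24 weeks. Macrophage shares of 9.92% and 8.83% in PS lie above the 5.95% and 5.73% of CT at both ages, and mast cells range from 1.07% to 4.09%.

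Within the mast cell class at 8 weeks, transcripts of cytokines and chemokines were lower in PS than in CT. Ccl1, a chemokine that attracts CCR8-bearing T cells, was at 85.2 CPM in PS and 588 CPM in CT, a ratio of 0.145 (0.0959 to 0.212). Il13, a type 2 cytokine, was at 217 against 732 CPM (ratio 0.297, 0.227 to 0.383), and Csf2, which encodes GM-CSF, had a ratio of 0.131 (0.0601 to 0.254). Il4 had a ratio of 0.404 (0.297 to 0.545) and the granule protease gene Ctsg one of 0.163 (0.0830 to 0.296). The class held 46 PS and 79 CT cells, with 363869 and 346826 UMIs. It was a single cluster, number 16, with a marker score of 5.69 for mast cells and a second-best score of 3.63 for basophils. Cyp11a1, a leading gene of the cluster, and Il4 were on the basophil marker list. No cluster took the basophil name, and whether this one also holds basophils was not tested.

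Of the 14 measured genes on the list of mast cell cytokines and chemokines, 8 were lower in PS beyond counting error and none was higher; the list's median ratio of 0.460 lay below all 10000 random lists matched on expression. Granule proteases had a median ratio of 0.587 (percentile 0.01), with 6 of 8 lower, including Cpa3 at 0.608 and Mcpt4 at 0.567. Mast cell surface receptors had a median of 0.651 (percentile 0.02), with Kit, the stem cell factor receptor, at 0.609. Granule and amine storage genes had 0.771 (percentile 0.33), and transcription factors 0.721 (percentile 0.985), with Gata2 at 0.405. Immediate-early genes had a median of 0.788 (percentile 0.8), with 10 of 18 lower, such as Jun at 0.624 and Dusp1 at 0.652, and Btg2 higher at 2.46. Higher lists were MHC class II presentation, with a median of 2.17 and 7 of 8 members higher, and lipid mediator synthesis, with a median of 1.77 and 5 of 5 higher, including Ltc4s at 1.96. Lists of IgE receptor signalling (median 0.899), heat-shock genes (1.03), glucocorticoid-induced genes (1.18), NF-kB targets (0.937), MHC class I presentation (1.06), oxidative phosphorylation (1.20) and glycolysis (1.09) lay within the middle 95% of random lists.

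The genes highest in PS mast cells at 8 weeks included genes of antigen-presenting cells, such as Mrc1, Ifi30 and Cd83. They were Bambi at a ratio of 48.6 (8.34 to 1957), Gdf15, Mrc1 at 20.0 (7.53 to 75.2), Dusp2, Zfp444, Ifi30 at 8.90 (3.84 to 25.3), Bcl2a1b, Sdc4, Cd83 at 6.07 (4.03 to 9.48), Scin, Avpi1 and Atp8b1. Of these, Bambi and Zfp444 had 78.4% and 94.7% of their PS UMIs in 1 cell. Without cells of a second type, as described below, Dusp2, Zfp444, Scin and Atp8b1 turned lower in PS. The other genes lowest in PS were Hmox1 at 0.0794 (0.0157 to 0.251), Car8 at 0.106, Mnat1, Cdh9, Dusp6, Cntn4, Maz and Anapc15. Mast-class cells that also carried many transcripts of a second cell type made up 43.5% of the PS and 17.7% of the CT cells, and 78.5% and 36.2% of the class's UMIs. Without those cells the ratio of Ccl1 was 0.433 (0.275 to 0.657), of Il13 0.415 (0.2789 to 0.6001), of Csf2 0.397 (0.164 to 0.837) and of Ctsg 0.340 (0.150 to 0.680), while Il4 was at 0.697 (0.458 to 1.03), Cpa3 at 1.03, Mcpt4 at 0.940 and Kit at 1.02. Of the lists still measured without them, cytokines and chemokines alone lay outside the middle 95% of random lists. Surface receptors turned to 1.02 and granule and amine storage to 1.04, and the MHC class II and lipid mediator lists had too few members.

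At 24 weeks Ccl1 and Il4 were again lower in PS mast cells, and interferon-stimulated genes were higher. Ccl1 was at 63.6 CPM in PS and 231 CPM in CT, a ratio of 0.275 (0.171 to 0.424), and Il4 at 310 against 696 CPM, a ratio of 0.445 (0.361 to 0.546). Of the 9 measured interferon-stimulated genes, 7 were higher, with a list median of 2.94 above all 10000 random lists. These were led by Irf7, a transcription factor of the interferon response, at 4.72 (2.64 to 8.84), Ifi27l2a at 4.70 (3.88 to 5.72) and Ifitm3 at 3.57 (2.95 to 4.33). The class held 182 PS and 263 CT cells, and cells with transcripts of a second type were 20.3% and 17.1% of them, with 53.5% and 45.0% of its UMIs. Without those cells Ccl1 was at 0.185 (0.0965 to 0.326) and Il4 at 0.480 (0.379 to 0.602), whereas Ifi27l2a, Irf7 and Ifitm3 were lower in PS, at log2 ratios of -1.28, -0.32 and -0.56, and the lists of interferon-stimulated, interferon-gamma response, complement and alternative macrophage genes had too few members to measure.

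Without cells of a second type Ly6c2, Ms4a4c and Rnf213 of the next genes turned lower in PS as well, at log2 ratios of -0.27, -0.44 and -1.66. Few UMIs may be left there, and the floor of 3 counts for a 0 can set the sign. The other mast cell genes named at 24 weeks were Ly6c2 at 11.2 (5.49 to 25.8), Id3, Ms4a4c, Arl5c, Sp100, Rnf213, Ssh2, Traf1 and Cxcl10 at 3.23 (2.12 to 4.98) among the higher, and Eprs, Mrc1, Ubb and Vim at 0.616 among the lower. Cytokines and chemokines had a median ratio of 0.914 (percentile 9.32), with 8 of 16 members lower and 3 higher; Il13 was at 0.656 (0.458 to 0.924), and Csf2 was higher at 1.87, with 82 of its 120 PS UMIs in 1 cell. Immediate-early genes had a median of 0.805 (percentile 0.04), with 14 of 18 lower, including Nr4a2 at 0.663. Alternative macrophage genes had 0.547 (percentile 0), with Mrc1 at 0.528 and Retnla, in the opposite direction, at 15.2. The interferon-gamma response list was at 1.62 (percentile 99.85), complement genes at 1.44 (percentile 99.64) and oxidative phosphorylation at 1.17 (percentile 98.2), and MHC class I presentation at 1.26 lay at the upper edge of the middle 95%, just outside it. Within the middle 95% of random lists lay granule proteases (median 0.857), granule and amine storage (1.00), surface receptors (0.868), lipid mediator synthesis (1.02), IgE receptor signalling (1.04), transcription factors (0.917), type 2 inflammation (0.844), cytotoxic genes (0.955), MHC class II (1.00), heat shock (1.06), glucocorticoid-induced genes (0.858), NF-kB targets (0.956) and glycolysis (0.883). Without cells of a second type the lists below the middle 95% were cytokines and chemokines, immediate-early, heat-shock, NF-kB and cytotoxic genes.

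The share of mast-class cells with a Ccl1 UMI was 29.1% in CT and 23.9% in PS at 8 weeks, and 11.4% and 5.50% at 24 weeks. In natural killer cells, which should lack it, the shares were 0.714%, 1.18%, 0.450% and 0.400% in the order CT and PS at 8 weeks, then CT and PS at 24 weeks. Median depths in that order were 3767, 5265, 1555 and 1059 UMIs in mast cells and 4648, 5574, 6538 and 4062 in natural killer cells. Thinned to 1000 UMIs per cell, which left out 15, 9, 89 and 86 mast-class cells, the Ccl1 shares were 17.2% (8.905 to 28.68), 13.5% (4.54 to 28.8), 10.9% (6.70 to 16.5) and 4.17% (1.15 to 10.3), so the gap at 8 weeks is within counting error. Il4 was found in 60.8%, 58.7%, 47.1% and 36.8% of cells, and in 23.4%, 29.7%, 23.0% and 20.8% after thinning, so its 8-week difference in CPM is not seen in the share of cells. In CT at 8 weeks 1 cell held 48.5% of the Ccl1 UMIs; without the top cell of each library the ratios were 0.179 (0.105 to 0.291) at 8 and 0.343 (0.199 to 0.563) at 24 weeks.

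**Figure D2:**
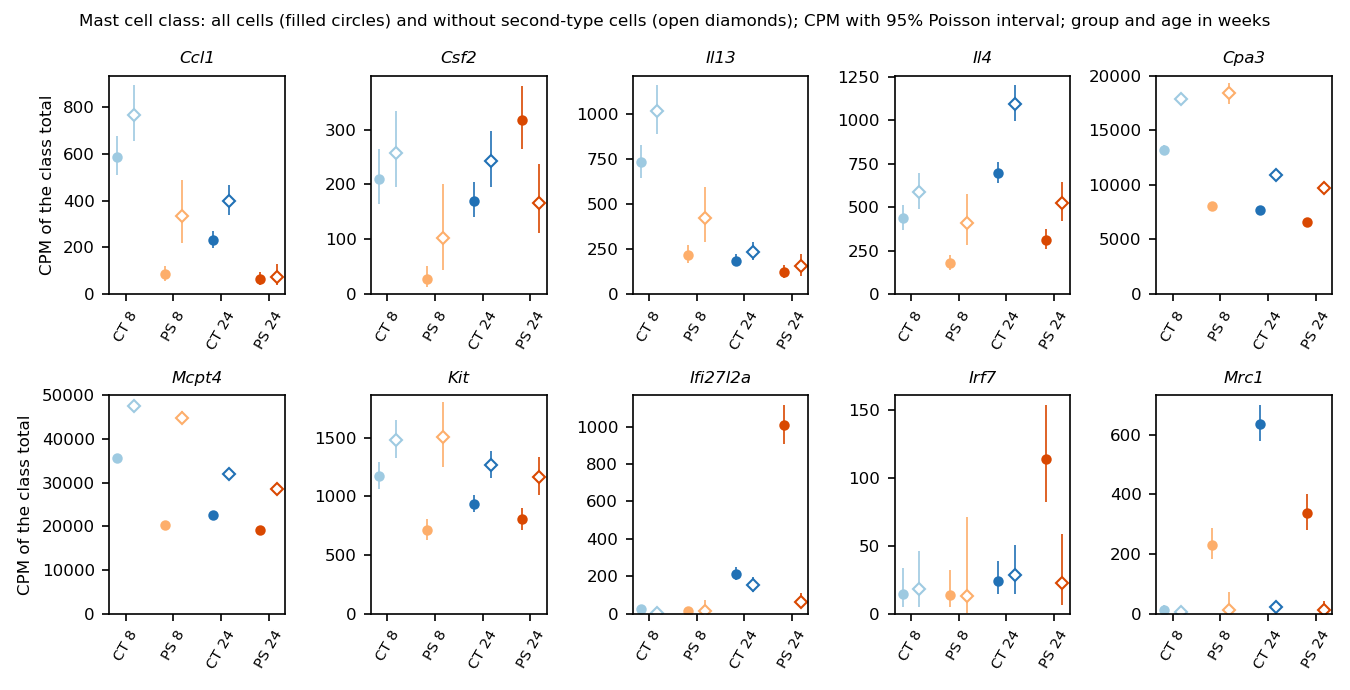
CPM of 10 genes in the mast cell class of the 4 libraries (CT and PS, age in weeks), with 95% Poisson intervals; filled circles use all mast-class cells and open diamonds leave out cells with transcripts of a second type. Ccl1 lies below CT in PS at both ages with either set of cells, whereas Ifi27l2a at 24 weeks, 1007 CPM in PS and 214 CPM in CT with all cells, turns around without them.

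Across the libraries, Ccl1 was the gene that passed the edgeR quasi-likelihood test for prenatal stress in mast cells with age as a term. Its log2 fold change was -2.38 (SE 0.285, Benjamini-Hochberg adjusted p = 0.0120, 5030 genes tested), and its UMI counts were 204 and 163 in the CT and 31 and 24 in the PS libraries at 8 and 24 weeks. Ccl1 (ENSMUSG00000020702) lies on chromosome 11 at 82176657 to 82305690 of mm10, as GENCODE M21 annotates it, and codes for protein. An unadjusted p under 0.05 was reached by 422 genes. The fit had 1 residual degree of freedom, which also holds any difference of the stress effect between ages. Over the alternatives the adjusted p of Ccl1 ranged from 1.18e-11 to 0.999, with 0.463 under DESeq2's size factors in edgeR, 0.0360 under DESeq2 and 0.563 (log2 fold change -1.76) without cells of a second type.

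In macrophages at 24 weeks, alternative macrophage genes were lower in PS and interferon-stimulated genes were higher. All 15 measured genes of that list were lower beyond counting error, with a median ratio of 0.405 below all 10000 random lists. Among them were Mrc1, the mannose receptor, at 0.504, the chemokine gene Ccl8 at 0.2497, Retnla at 0.265 and Cd209f at 0.102 (0.0812 to 0.128). Arg1, which encodes arginase and marks type 2 activation, was at 3.24 CPM in PS (21 UMIs in 11 of 738 cells) and 407 CPM in CT (1673 UMIs in 29 of 369 cells), a ratio of 0.00796 (0.00491 to 0.0122). Ccl24, an eosinophil chemoattractant, was at 0.182 (0.157 to 0.209), Ccl17 at 0.170 and Mmp13 at 0.127.

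The type 2 inflammation list in 24-week macrophages had a median ratio of 0.531 (percentile 0), with 7 of 11 members lower and Ccl22 higher at 1.63. Of 17 interferon-stimulated genes 15 were higher and 1, Ifit1, was lower, with a median of 1.76 (percentile 100). Irf7 was at 3.68 (3.13 to 4.35), Ifit3 at 3.33 and Ifi27l2a at 2.21, and Ly6c2, a marker of recently arrived monocytes, at 6.68 (5.54 to 8.14). Ly6a and Plac8 were at 3.04 and 3.03. Cytotoxic lymphocyte genes (median 1.61) and mast cell proteases (1.87, 5 of 5 higher), which belong to other cells, were also higher in this class, at CPM values under 10% of those in their own class, and with doublets kept the proteases turned lower, at 0.682. At 8 weeks Retnla was at 0.386 (0.365 to 0.407), Nrg1 at 0.341, Exoc3l2 at 0.459 and Thbs1, which turned higher under 3 of the alternatives, at 0.457 in PS macrophages, with Gpnmb at 6.27 (4.51 to 8.93), Col1a2 at 1.98 and Tnfaip2 at 1.75. The free RNA list of structural skin cells was at 1.74 there, with 11 of 13 members higher.

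Arg1 was also the gene that passed edgeR's test for prenatal stress in macrophages, with a log2 fold change of -6.96 (SE 0.311, Benjamini-Hochberg adjusted p = 0.00103, 10918 genes tested, 376 with an unadjusted p under 0.05). It lies on chromosome 10 at 24915221 to 24927484 of mm10 (ENSMUSG00000019987). At 8 weeks Arg1 had 2 UMIs in CT and 0 in PS macrophages, so the call rests on the 24-week libraries. Over the alternatives its adjusted p ranged from 1.70e-67 to 1.00, with 0.697 under DESeq2. The share of macrophages with an Arg1 UMI was 7.86% in CT and 1.49% in PS at 24 weeks, and 5.79% and 0% of 689 PS cells after thinning. Natural killer cells had 0.901% and 0%, with median depths of 6538 and 4062 UMIs against 8704 and 6580 in macrophages. In monocytes at 24 weeks Arg1 had 2 UMIs in PS and 282 in CT, a ratio of 0.0105 (0.00126 to 0.0382), with the 282 in 6 cells.

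Interferon-stimulated genes were higher in PS in other classes at 24 weeks as well. Their median ratio was 2.44 in conventional dendritic cells 1 (10 of 12 higher), 2.12 in conventional dendritic cells 2 (13 of 16 higher) and 1.73 in αβ T cells (12 of 15 higher, Isg15 lower), above all 10000 random lists in each. Ifi27l2a was at 6.43 (5.35 to 7.77), 2.52 and 2.89 (2.64 to 3.16) in these classes, and the chemokine gene Cxcl10 at 4.10 (3.43 to 4.93) in conventional dendritic cells 2. Other genes in dendritic cells 1 were Plac8 at 3.37, Hspa1a, Slfn5, Cdk11b, Cwc25, Gem at 0.362 and Rgcc, and in dendritic cells 2 Ly6c2 at 2.79, Ifitm3 at 2.29, Mmp12 at 0.391, Kcnma1 and Gem at 0.487. Complement genes in dendritic cells 2 were at 4.48, with C1qb at 7.81 and under 10% of its macrophage level. Regulatory T cell genes there were at 2.04, and cytotoxic genes in dendritic cells 1 at 0.473, with the named members of each also under 10% of their level in other classes; with doublets kept the cytotoxic list turned higher, at a log2 ratio of 0.5512. Monocytes had Oasl1 at 2.21, Ifi27l2a at 1.96, Chil3 at 0.334, Hmox1 at 0.397 and Cxcl1 at 0.476.

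**Figure D3:**
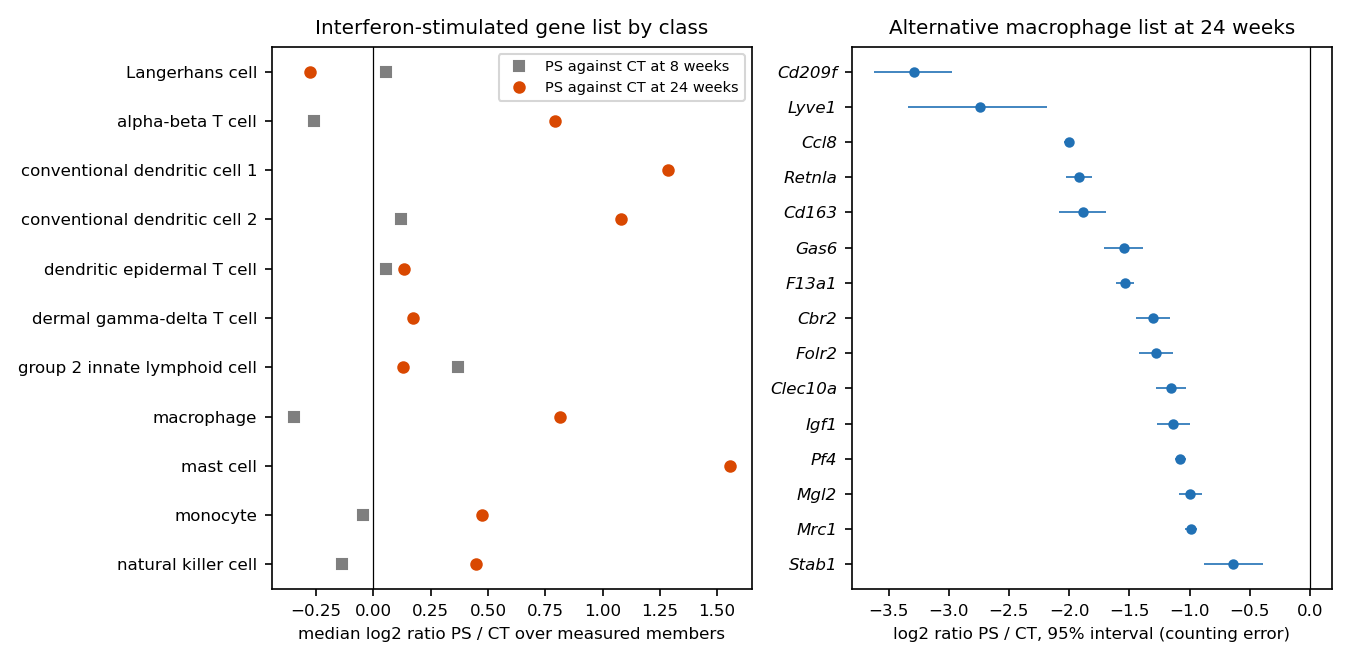
Left, median log2 ratio of PS to CT over the measured interferon-stimulated genes of each class at 8 weeks (squares) and 24 weeks (circles). Right, log2 ratio with its 95% interval (counting error) for the 15 alternative macrophage genes in macrophages at 24 weeks, all below 0, with Cd209f lowest.

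In αβ T cells at 24 weeks, type 17 genes were higher and type 2 genes lower in PS. Il17a, the signature cytokine of type 17 T cells, was at 150 CPM in PS (587 UMIs) and 1.94 CPM in CT (8 UMIs), a ratio of 77.3 (39.0 to 180). Il17a (ENSMUSG00000025929) lies on chromosome 1 at 20730905 to 20734496 of mm10. Il17f was at 20.6, the receptor gene Il23r at 21.4, and Il22, with 88 UMIs against 0, at least 30.9-fold higher against a floor of 3 counts. The type 17 list had a median of 19.3, with 7 of 9 members higher, and the type 2 list one of 0.412, with 5 of 6 lower, including Il5 at 0.0549 and Il13 at 0.452. An Il17a UMI was found in 88 of 1028 PS and 1 of 647 CT cells, 8.56% and 0.155%, and in 5.75% and 0.155% after thinning. Macrophages had 1.63% and 0.542%, at median depths of 6580 and 8704 UMIs against 3338 and 5792 in αβ T cells. Lamc1 was at 3.74, Ifng at 0.507 (0.460 to 0.557) and Fos at 0.480, and Plxnc1, Fgl2 and Ubb also met the naming rule. The make-up of the class differed here too: cluster 15, led by Gzmc, Tbx21 and Ifng, held 37.9% of its CT and 29.0% of its PS cells, and cluster 26, led by Lef1, 16.4% and 30.2%.

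At 8 weeks PS αβ T cells had lower levels of CD8 chain genes, Cd8b1 at 0.302 (0.226 to 0.397) and Cd8a at 0.396 (0.301 to 0.514), and of Ccl4 at 0.377 and Ifi27l2a at 0.463. Higher genes were Ctnnd2 at 3.88, Ssna1, Ctla2b and Areg at 2.19 (1.94 to 2.47). The make-up of the class differed: cluster 12, which Cd8a leads among others, held 44.0% of its CT and 30.8% of its PS cells, and cluster 15 24.3% and 37.4%. Cluster 15 carried γδ receptor transcripts. In CT and PS at 8 weeks, then CT and PS at 24 weeks, its Trdc was at 327, 673, 771 and 323 CPM. Its Trac was at 318, 257, 269 and 240 CPM, below Trdc in each library. None of its 10 leading genes was on the αβ T cell marker list. The αβ T cell class may therefore include γδ T cells at both ages.

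In dendritic epidermal T cells Cd163l1 and Havcr2 were higher in PS at both ages. Cd163l1, a scavenger receptor gene of γδ T cells, was at 138 against 46.7 CPM at 8 weeks, a ratio of 2.96 (2.69 to 3.25), and at 199 against 69.6 CPM at 24 weeks, a ratio of 2.86 (2.56 to 3.18). It lies on chromosome 7 at 140218267 to 140231145 of mm10 (ENSMUSG00000025461). Havcr2, which encodes the inhibitory receptor TIM-3, was at 2.74 (2.55 to 2.95) and 2.50 (2.26 to 2.76). The class's Trdc and Trdv4 were lower in PS at 24 weeks, at 1824 against 3184 and 381 against 860 CPM, but higher in PS at 8 weeks. In the PS 24-week library cluster 28 had Cd163l1 at 741 and Havcr2 at 510 CPM. Whether the make-up of the class moved toward such cells was not tested. Of 1878 genes measured at both ages, Cd163l1 and Havcr2 were the 2 at least 2-fold higher in PS at both, against 0.00320 for independent lists of 3 and 2 genes. Both were high in cluster 28 and may move together, and this figure does not measure differences between pools. At 24 weeks Hspa1b was at 2.51 and Scin at 1.93, with Ier5 at 0.557, Mylk at 0.563, Ubb and Sap18 lower, and most CT cells lay in cluster 6 and most PS cells in cluster 8. Ubb and Sap18 were lower in PS at 24 weeks in 8 of 8 classes, at 0.457 to 0.663 and 0.545 to 0.864, and Ubb is uncertain because 63.3% of its 3′ windows are shared with other genes. At 8 weeks Slc35f3 was at 1.72, with Pcdh7, Itsn1 and Rcbtb2 lower. The type 17 list was at 0.595 at 24 weeks, with Il22 at 0.504, and at 8 weeks MHC class II genes were at 1.58 and alternative macrophage genes at 1.501, at levels under 10% of those in their own classes, and with doublets kept the latter were at 0.947.

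Dermal γδ T cells at 24 weeks carried more transcripts of cytotoxic genes in PS, with a median ratio of 7.46 and 5 of 5 members higher. Nkg7, a cytotoxic granule gene, was at 9.52 (6.83 to 13.6), with a UMI in 73 of 594 PS and 15 of 287 CT cells, so most cells of the class had none. Prf1, perforin, was at 7.46 (4.00 to 15.4), though Prf1 and Gzmc were under 10% of their level in another class. Kcnma1 was at 13.4 (8.42 to 22.5), Slc24a3 at 6.27 and Ctla2a at 6.12, and Il17f at 0.381, Ccr6 at 0.340, Tnfsf11 at 0.309 and Cxcl10 at 0.355, while Il17a was at 821 against 597 CPM and Il1r1 at 1.48. Kcnma1 and Ctla2a are among the leading genes of cluster 0 of the dendritic epidermal T cells. With doublets kept the median log2 ratio of the 4 higher genes was 1.37 instead of 2.95. In group 2 innate lymphoid cells at 24 weeks Trf was at 5.09 and Ccser2 at 2.57, with Magi1 and Ubb lower and the type 17 list at 0.474. At 8 weeks they had Il5 at 1.97 (1.60 to 2.43), Plekhg1, Alcam and Il17a (136 UMIs in 6 cells) higher, and Ccl1 at 0.0624 (0.0198 to 0.151), Abcb1b, Stat5b and Tnfsf8 lower.

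Smaller sets of genes differed in the other classes. At 8 weeks conventional dendritic cells 2 had Ifitm1 at 3.80 (3.43 to 4.21), Ccr7, the lymph node homing receptor gene, at 2.21 (1.94 to 2.52), Ptgs2 at 1.87 and Timd4 at 0.450, with Prkcb and Adam23 also lower. Monocytes had Ifitm1 at 5.52 (3.99 to 7.78), Chil3 at 3.02 (2.44 to 3.77), Fmnl2, Clec4n, and complement genes at a median of 1.57, with Abcb1b, Dgkg, F10 and Fam49a lower. Natural killer cells had Klf4 at 2.03 and Cxcl10 at 0.341 at 8 weeks, and Cxcl10 at 2.91 and Ly6c2 at 0.467 at 24 weeks. After the exclusions of genes under 10% of their level in another class and of unnamed gene models, no Langerhans cell gene differed at least 2-fold at 8 weeks. There cytotoxic genes (2.39), complement genes (1.52) and regulatory T cell genes (0.657) differed at levels under 10% of those in other classes. At 24 weeks Langerhans cells had Tcaf2 at 1.73, with Sap18 and Ubb lower. The free RNA list was at 0.475 in dendritic epidermal T cells at 8 weeks, 1.68 at 24 weeks, and 0.618 in Langerhans cells at 24 weeks. With the stricter filter the 1.68 was 0.969, and the Langerhans cell value was 1.04 at resolution 2 and 1.12 with variable genes over all cells, so the direction at 24 weeks depends on the processing.

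Between 8 and 24 weeks of age, αβ T cells, dermal γδ T cells, group 2 innate lymphoid cells and mast cells took larger shares and dendritic epidermal T cells smaller ones, in both CT and PS. Mast cells were 3.51-fold (2.72 to 4.58) higher at 24 weeks in CT and 2.04-fold (1.47 to 2.89) in PS, where cells with at least 1000 UMIs gave 1.37 (0.9295 to 2.062), an interval that includes 1. Dermal γδ T cells were 3.12-fold (2.47 to 3.97) and 4.65-fold (3.60 to 6.09) higher, αβ T cells 1.87-fold and 2.68-fold, and group 2 innate lymphoid cells 1.74-fold and 1.77-fold. Dendritic epidermal T cells were at 0.577 and 0.295 of their 8-week share by the named clusters, and at 0.594 and 0.578 with cluster 28. Neutrophils were 3.64-fold (2.67 to 5.05) higher in CT but at 0.370 (0.255 to 0.533) in PS, and mature dendritic cells 2.48-fold and 3.67-fold higher.

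In mast cells, edgeR's test for age with stress as a term called 279 genes that rose and 206 that fell from 8 to 24 weeks (Benjamini-Hochberg adjusted p under 0.05, 5030 genes tested). The CT and PS libraries of each age served as its replicates. Handling or read counting shared by both libraries of an age cannot be told from age here. Ccl4 and Il1b, inflammatory mediators, rose by 5.12 (SE 0.268, adjusted p = 1.06e-06) and 5.53 (SE 0.327, adjusted p = 2.25e-06) on the log2 scale, and Gzma, Rsad2, Plac8 and Tnfsf9 also rose. The largest rises were those of Cxcl10 at 8.68 and of Cd209a, Clec4e and Cd209d at 8.28, 8.21 and 7.57. Cxcl10 had 37 and 64 UMIs at 24 weeks in CT and PS and 0 in both 8-week libraries. Nwd1, Lsmem1 and Eldr fell, with log2 fold changes of -3.88 (SE 0.346, adjusted p = 5.31e-05), -3.25 and -3.41, as did Ttc39c, Mmp9, Fam189a2, Egfl8, Wnk2, Gna15 and Myo10. Without cells of a second type edgeR called 55 genes that rose and 45 that fell, and Nwd1, Lsmem1, Eldr, Il1b and Gzma passed at log2 fold changes of -4.11, -3.98, -5.19, 4.98 and 5.90. Ccl4 passed at a smaller 1.78 (adjusted p = 0.0470), and Rsad2, Plac8, Tnfsf9, Cxcl10, Cd209a, Clec4e and Cd209d were not among the genes tested there.

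Lists that differed with age in CT and PS mast cells alike included cytokines and chemokines (median ratios 1.57 and 2.77), NF-kB targets (1.66 and 1.54) and lipid mediator synthesis (0.528 and 0.547). Without cells of a second type the cytokine and NF-kB lists lay within the middle 95% of random lists in both, with cytokines and chemokines at 0.960 in CT. Other lists were also higher with all cells: alternative macrophage genes (21.0 and 2.55), complement (8.29 and 3.43), interferon-stimulated (7.26 and 7.31), cytotoxic (3.44 and 2.89) and type 2 inflammation genes (1.60 and 2.20). Of these, only the cytotoxic list, in CT, could still be measured without those cells, and it stayed above the middle 95%. In CT the named genes were Ccl8 at 198 (35.3 to 7829), Pf4, Mrc1, Dab2, Wfdc17 and Gdf15 upward, and Eldr, Nwd1 at 0.0896 (0.0614 to 0.128), Lsmem1, Ctsg at 0.104, Fgf13 and Mmp9 downward. The values of Pf4 and Fgf13 turned the other way without cells of a second type. Few UMIs may be left there, and the floor of 3 counts for a 0 can set the sign. In PS they were Ifi27l2a at 73.3 (31.1 to 227), Ccr2, Ly6c2, Rsad2, Ccl4 at 39.6 (21.9 to 79.9) and Tnip3 upward, and Atp8b1, Nwd1, Cd207, H2-M5, Ttc39c and Baiap2 downward. Without cells of a second type the values of Atp8b1 and Cd207 turned upward, with the same caution, and with equal weight per cell Ly6c2 turned downward. The median log2 size of the named genes without cells of a second type was 1.98 instead of 4.34 in CT and 1.17 instead of 5.32 in PS. Cells with transcripts of a second type held 36.2%, 78.5%, 45.0% and 53.5% of the mast-class UMIs in CT and PS at 8 weeks and CT and PS at 24 weeks.

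In macrophages the age test, with the same limit, called 210 genes that rose and 109 that fell (10918 genes tested). NF-kB targets were higher at 24 weeks, with median ratios of 1.82 in CT (17 of 18 members higher) and 1.51 in PS (15 of 18), and Il1b at 1.65 and 2.68 and Tnf at 3.54 and 1.95. Type 17 genes were at 1.97 and 2.04, regulatory T cell genes at 1.51 and 1.64, with Il10 at 2.34 and 1.85, and cell cycle genes at 2.59 and 1.82. Other members of these lists, such as Il17a, Icos, Il2ra and Ube2c, were under 10% of their level in other classes. The largest rises by edgeR included keratin genes, Krt35 at 9.51, Krt71 at 7.66 and Krt25 at 7.62 on the log2 scale, and Il23r at 7.47 and Blk at 7.33, which lead the dermal γδ T cells. Arg1 (8.85), Sgcz, Hlf, Efna5 (6.10) and Dthd1 were the others. Dennd5b fell, with -3.28 (adjusted p = 0.00199), as did Cfap61, Tmprss9, Exoc3l2, Bbof1, Grik3, Gstp1, Ptcra, Tcim and Dynlt1c. Of these, Gstp1 and Dynlt1c were lower at 24 weeks in 8 of 8 classes in both CT and PS. Gstp1 shares 90.9% of its 3′ windows with other genes. In CT, Arg1 had 1673 UMIs at 24 weeks and 2 at 8 weeks, a ratio of 451 (125 to 3726), Mmp13 was at 5.45 and Ptgs2 at 4.86, with Exoc3l2, Slfn4 and Ly6c2 lower. In PS, Htr7, Gcnt2 and Mir155hg were higher, and Cd209f at 0.0997 and Col1a1 at 0.130 lower.

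Other classes had age differences shared by CT and PS. Langerhans cells had Sgcz at 7.60 (6.82 to 8.48) in CT and 6.84 (6.13 to 7.66) in PS. Group 2 innate lymphoid cells had Tmeff2 at 23.0 (12.0 to 50.7) and 40.1, and Csf2 at 0.206 and 0.108. Monocytes had NF-kB targets at 1.87 and 2.24 and interferon-gamma response genes at 1.97 and 2.48. In CT the naming rule also picked Adgrl2, Olfm3 and Col27a1 in αβ T cells, Ncam1 at 4.81 and Mest at 2.56, a leading gene of cluster 6, in dendritic epidermal T cells, Isg15 at 4.11 in conventional dendritic cells 2, Zeb2 at 9.10 in group 2 innate lymphoid cells, and Dscam and Inpp4b in natural killer cells. In PS it also named Il17a at 12.4 (7.47 to 22.4) in αβ T cells, Vegfa at 4.52 and Dnajc6 in dendritic epidermal T cells, Ifih1 at 4.72 in conventional dendritic cells 2, Gpr55 at 108 (19.1 to 4267) in group 2 innate lymphoid cells, and Oasl1 at 7.09 and Isg15 at 4.69 in monocytes. Whether CT and PS differ in these genes was not tested. AY036118, Gstp1, Eno1, Hmgn2, Bcl2a1d and Ubb were lower at 24 weeks in several classes and are uncertain, since their 3′ ends share sequence with other genes.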

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

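The tests of the mast cell and cluster 28 patterns were chosen after the results were seen; both tests of shared sequence were written before they were run. None of the differences between ages below was tested.

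In the next results, save where stated, the difference between PS and CT ran in opposite directions at 8 and 24 weeks. The neutrophil share was 2.20-fold in PS at 8 weeks and 0.223-fold at 24 weeks, a log2 difference of -3.301. In macrophages the median ratio of interferon-stimulated genes went from 0.786 to 1.76 (log2 difference 1.161), of cytotoxic genes from 0.786 to 1.61 (1.034), of NF-kB targets from 1.08 to 0.884 (-0.2944) and of glucocorticoid-induced genes from 1.21 to 0.743 (-0.6989). In group 2 innate lymphoid cells glucocorticoid-induced genes went from 1.23 to 0.868 (-0.5051). The free RNA list of structural skin cells went from 0.475 to 1.68 in dendritic epidermal T cells (1.822). In conventional dendritic cells 2 its medians were 1.30 and 0.724 (-0.8464), with 0 of 5 members beyond counting error at 8 weeks, so a change of direction is not shown there. Others are lost under 1 alternative each: in macrophages at 8 weeks the NF-kB list had a log2 ratio of -0.02212 with variable genes over all cells and the cytotoxic list 0.01012 with equal weight per cell, and the free RNA list in dendritic epidermal T cells at 24 weeks had -0.04501 with the stricter filter. The glycolysis and hypoxia list went from 1.20 to 0.933 in Langerhans cells (-0.3646), 1.25 to 0.868 in αβ T cells (-0.5211), 1.19 to 0.860 in conventional dendritic cells 2 (-0.4629), 1.12 to 0.868 in dendritic epidermal T cells (-0.3659), 1.498 to 0.890 in group 2 innate lymphoid cells (-0.7513) and 1.39 to 0.748 in monocytes (-0.8955).

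Mast-class cells with transcripts of a second type may be droplets that hold 2 cells, or mast cells stuck to or loaded with another cell. Their number does not decide between these, but the UMIs of the genes named as higher in PS lie mostly in them: a median of 98.81% of the PS UMIs of those genes lay in such cells at 8 weeks and 95.29% at 24 weeks, where these cells held 78.5% and 53.5% of the class's UMIs. Lower Ccl1 and Il13 remained when these cells were left out. The 8-week ratios were then 0.4329 and 0.4151, with intervals below 1, but Il4 was at 0.697 (0.458 to 1.03). These intervals treat UMIs from 26 PS and 65 CT cells as independent. They therefore do not exclude dilution by the RNA of second-type cells as the whole cause. With all cells, an Il13 UMI was found in 58.2% of CT and 52.2% of PS cells at 8 weeks. After thinning it was 34.4% (23.0 to 47.3) and 21.6% (9.83 to 38.2), within counting error. The top cell of each library alone is excluded as the cause of lower Ccl1. Without it the ratios were 0.1791 at 8 and 0.3432 at 24 weeks. The top cell and the second-type cells were not left out together, so both combined stay open for Ccl1. Lower Ccl1 could reflect prenatal stress, or differences between pools or in handling, which 1 library per group cannot tell apart.

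The cell type of cluster 28 was left open. Tcrg-C1, Cd3e and Fcer1g were at 722, 2170 and 2506 CPM against 697, 2026 and 2519 in the named dendritic epidermal T cell clusters of the PS 24-week library, but Trdc, Trdv4, Xcl1 and Chl1 were at 900, 93.2, 369 and 35.8 against 1824, 381, 1129 and 204, and Cd163l1 at 741 against 199. Its median UMIs per cell were 1.069 times those of the named clusters, which excludes doublets under the limit set. Its mitochondrial percentage was 0.8767 times theirs, so it was not raised. Damaged cells are not excluded by this, because cells with high mitochondrial percentages had been filtered out before. Damage shared with the named clusters of the same library would not show either. A shift of the whole library stays open: 0 of 25 other clusters had 80% or more of their cells from it, but shifts within shared clusters would not show there, and dendritic epidermal T cell cluster 0 held 811, 416, 87 and 20 cells in CT and PS at 8 weeks and CT and PS at 24 weeks. With 1 library per group, a cluster mostly of 1 library may be that library, not a type: prenatal stress and a single mouse of the pool cannot be told apart.

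Genes whose 3′ ends share sequence with other genes were lower at 24 than at 8 weeks, with a median log2 ratio of -0.1725 in CT and -0.1676 in PS over 127 of 6730 genes, below all random lists. This fits reads shared between near-identical genes being counted differently in the libraries of the 2 ages, possibly by another software version or reference, which was not tested. AY036118, with 100% of its 3′ windows shared, was at 472, 550, 89.4 and 62.9 CPM over all cells in CT and PS at 8 weeks and CT and PS at 24 weeks, whereas Sap18, with 0% shared, was at 192, 174, 123 and 63.2 CPM, so shared sequence as searched does not cover every such gene. Lower depth at 24 weeks is excluded in CT, where median UMIs were 1.377 times those at 8 weeks. For the glycolysis and hypoxia list, shared sequence of the kind searched is excluded as the main cause. Over the 13 to 15 members per class measured at both ages, fewer than for the values above, the median difference over 6 classes was -0.5693, and without the shared members -0.5404. The search took exact matches in windows of 60 bases, so near-identical copies with mismatches would be missed.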

How the results depend on the processing

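Of 3374 alternative values, 2868 were counted as unchanged, 472 as moved and 34 as reversed. Unchanged means within the 95% counting interval of the reported value for shares and genes, within the median half-width of those intervals for the median of the named mast cell genes, within a log2 of 0.25 for list medians and within 1.5-fold for counts of calls or lists, so that 713 and 330 age calls in mast cells count as unchanged beside 485. No paired analysis was possible because the groups share no mice or litters in the labels, only replicate number 1. With 1 library per group none could be left out. In every alternative Ccl1 stayed lower in PS mast cells, with edgeR or DESeq2 log2 fold changes from -1.757 to -2.556, and Arg1 in macrophages, from -4.013 to -6.961. At 24 weeks the alternative macrophage list ranged from -1.115 to -1.415 in macrophages, their interferon-stimulated list from 0.7735 to 0.8767 and Il17a in αβ T cells from 5.732 to 6.332. The macrophage share was 0.7154 to 0.9162 at 8 weeks and 0.3169 (doublets kept) to 0.8071 at 24 weeks, and the natural killer cell share 0.5024 to 0.5682 and 0.7649 to 0.9785. Cells with Xist UMIs only were not run, since 13 cells had one, nor Y-linked UMIs only for mast cells, of which 32 had one in PS at 8 weeks. Leaving out mast-class cells of a second type, for shares as well as genes, and counting cluster 28 with the dendritic epidermal T cells, were chosen after seeing the data. Values below are log2 ratios unless counts are named, and except where the setting itself takes out cells or genes, the cause was not tested. Shallow mast cells limit the shares: with at least 1000 UMIs per cell the mast cell share was -1.213 instead of -0.9072 for PS against CT at 24 weeks and 0.4557 instead of 1.03 for age in PS.

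Without second-type cells, PS against CT at 8 weeks in mast cells gave Dusp2 -0.4989 (reported 3.253), Zfp444, Scin and Atp8b1 -0.08391 each, the granule and amine storage list 0.04966 (-0.375) and the surface receptor list 0.02615 (-0.6182). At 24 weeks Rnf213 was -1.663, Ifi27l2a -1.279, Ifitm3 -0.5639, Ms4a4c -0.4411, Irf7 -0.3155 and Ly6c2 -0.2712, all reported as higher. For age in CT, Pf4 was -0.2236 (5.891), Fgf13 0.7764 (-3.102) and the cytokine and chemokine list -0.05891 (0.6471). For age in PS, Atp8b1 and Cd207 were 0.4192 each. Where few UMIs are left, the floor of 3 counts for a 0 can set the sign of a gene's value. This may hold for values shared by several genes, whose direction is not shown. The median log2 size of the named mast cell genes in their reported direction was 1.501 instead of 2.687 at 8 weeks, 0.6545 instead of 1.819 at 24 weeks, 1.984 instead of 4.336 for age in CT and 1.166 instead of 5.324 for age in PS. Mast cell lists outside the middle 95% of random lists were 1 instead of 8 at 8 weeks, 4 instead of 10 for age in CT and 2 instead of 15 for age in PS.

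With each cell weighted equally, such lists were 5 at 8 weeks and 6 for age in PS, the named mast cell genes had 1.162 at 24 weeks, Ly6c2 in mast cells for age in PS was -0.3206 (5.702), cytotoxic genes in macrophages at 8 weeks 0.01012 (-0.3468) and free RNA in conventional dendritic cells 2 at 8 weeks -1.244 (0.3809). With at least 100 UMIs per gene the genes picked at 8 weeks had 1.456. Thbs1 in macrophages at 8 weeks (-1.128) was 0.07151 with the stricter filter, 0.05211 with doublets kept and 0.625 with variable genes over all cells. With doublets kept the monocyte share was 0.2895 (-0.2965) at 24 weeks and -0.176 (0.3832) for age in CT, where resolution 2.0 gave -0.04767; Cxcl10 in monocytes for age in CT was -0.2131 (2.595). The same setting gave 0.5512 (-1.081) for cytotoxic genes in conventional dendritic cells 1 and -0.5528 (0.906) for mast cell proteases in macrophages at 24 weeks, and -0.07885 (0.5856) for alternative macrophage genes in dendritic epidermal T cells at 8 weeks. Free RNA at 24 weeks was -0.04501 (0.7484) in dendritic epidermal T cells with the stricter filter, and in Langerhans cells (-0.6943) 0.05131 at resolution 2.0 and 0.1692 with variable genes over all cells, where NF-kB targets in macrophages at 8 weeks were -0.02212 (0.1161).

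For prenatal stress in mast cells, where edgeR called 1 gene, it called 0 with DESeq2's size factors (359 genes with unadjusted p under 0.05), 0 without the age term (92), 0 with doublets kept (332), 0 at resolution 2.0 (373) and 0 without second-type cells (90); it called 65 without a filter, 58 with the stricter cell filter and 5 with variable genes over all cells, and DESeq2 called 1. In macrophages, with 1 reported, edgeR called 0 without the age term (77), 104 without a filter, 9 with the stricter filter, 30 with doublets kept, 2 at resolution 2.0 and 27 with Y-linked cells only, and DESeq2 2. Age calls in mast cells (485) were 253 with DESeq2's size factors, 750 without a filter, 216 without the stress term, 100 without second-type cells and 122 by DESeq2. Age calls in macrophages (319) were 1430 without a filter, 524 without the stress term, 766 with the stricter filter, 1829 with doublets kept, 668 at resolution 2.0, 557 with variable genes over all cells and 982 with Y-linked cells only.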

Other observations

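The Il17a-expressing αβ T cells of PS skin at 24 weeks had αβ receptor transcripts and more Cd4 than Cd8a. In the 88 cells with an Il17a UMI, Trac, the α chain constant gene, was at 432 CPM and Trbc2 at 644 CPM, with Trdc of γδ T cells at 186 CPM, against 325, 719 and 140 CPM in the 940 αβ T cells without one. Cd4 was at 192 CPM and Cd8a at 17.2 CPM, against 66.6 and 140 CPM, and Foxp3, the regulatory T cell factor, was at 0 and 1.68 CPM. In the dermal γδ T cells of the same library Trdc was at 1507 CPM, Trac at 57.1 CPM and Trbc2 at 474 CPM. Of the 587 Il17a UMIs, 557 lay in cluster 12. Over all PS cells of cluster 12 at 24 weeks Trdc was at 57.3 CPM, below the 186 CPM of the cells with an Il17a UMI. Cluster 15, also of this class, had it at 323 CPM. Some γδ T cells among the 88 are therefore not excluded. These genes were chosen after the Il17a values were seen.

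Gm47283 (ENSMUSG00000096768), a protein-coding gene model on chromosome Y at 90784738 to 90816464 of mm10, was lower in PS in 8 of 8 classes at both ages. Over all cells it was at 765 CPM in CT and 345 CPM in PS at 8 weeks, and at 723 and 206 CPM at 24 weeks. The median ratio over classes was 0.453 and 0.289, and 15.25% of its 3′ windows share sequence with another gene. It was singled out after its values were seen. The labels do not say whether CT and PS litters had the same sires or breeding line. The Y-linked genes Ddx3y and Uty were also lower in PS over all cells, with smaller gaps. In CT and PS, Ddx3y was at 271 and 224.7 CPM at 8 weeks and 328.5 and 299.7 at 24 weeks. Uty was at 671.3 and 442.2, then 617.9 and 546.5. Gm47283 alone does not show a difference of Y chromosome between the groups. Such a difference was not tested, and would leave any PS against CT difference open to a difference of line.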
